A study of Mus musculus with 3 samples.

How the data were processed

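Per the labels, stromal vascular cells were isolated from inguinal white fat of C57BL/6 mice with a Miltenyi dissociation kit and made into 10x Chromium 3' v3 libraries. One library each came from saline-treated mice, mice kept at 4 C for 3 days and mice given CL (the labels' short name for the β3-adrenergic agonist; 1 mg/kg, intraperitoneal) for 3 days. Per the file headers, the authors' deposited matrices hold raw UMI counts per gene and barcode from Cell Ranger 3.0.2, and the labels name the genome build mm10. The values are whole numbers with totals that differ between barcodes, as raw counts have, and every barcode has at least 500 UMIs. Gene annotation, aligner settings, cell calling, the number of animals pooled and their sex were not given in the sources used here. The matrices list 28692 genes, of which 28416 were matched by Ensembl ID to GENCODE M21 for coordinates, and Selenop was read under its older symbol Sepp1.

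Barcodes with under 500 detected genes (1283 saline, 1007 cold and 1147 CL) or over 15% mitochondrial UMIs (501, 682 and 306) were left out, which kept 81.7%, 76.5% and 84.4%. Doublets were called in each library with Scrublet as in scanpy, with an expected rate of 8e-06 times the number of cells and its automatic score limit. The limits came out at 0.256, 0.373 and 0.293 and removed 96, 4 and 77 cells. The cold limit removed 0.1% of cells against 1.53% and 1.15%, so doublets remain in that library. A common score limit of 0.2, chosen after seeing this, was tried as an alternative. It took out 125 saline, 15 cold and 113 CL cells, so it too removed few cold cells and leaves the effect of cold doublets open. The 16661 cells left by the automatic limits held 69664610 UMIs. Free RNA was not subtracted.

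Counts were scaled to 10000 per cell and log-transformed, 2000 highly variable genes were taken, and 30 principal components gave 15 nearest neighbours per cell. Leiden clusters at resolution 1 were made over the 3 libraries together, with no batch integration and seed 1. Each cluster took the class with the highest mean log2 fold of fixed markers over all other cells (24 classes, pseudocount of 20 CPM). It needed at least 3 markers at 50 CPM and a log2 fold of 1, and no more markers of another class than of its own among its 10 top genes. After the clusters were seen, a cluster with no own marker among these genes was also required to score 1.5 times its second class. The naming limits were not among the choices fixed before the data were examined. Monocyte-like and macrophage-like cells were then also joined to a single class for shares, since the markers of these classes overlap. Unnamed clusters held 0.761% of the saline, 2.59% of the cold and 0.226% of the CL cells, and counted as immune-like from 100 CPM of Ptprc on.

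Shares of cells are given with exact Clopper-Pearson intervals, of immune-like and of non-immune-like cells apart, so that a class on 1 side does not dilute the other. Log2 ratios of shares, and of cells per endothelial-like cell, have normal-approximation intervals on the log scale. For expression, UMIs were summed over the cells of a class in each library and given as CPM with exact Poisson intervals, and ratios with exact conditional binomial intervals. The main classes were ASPC-like, macrophage-like, endothelial-like and T cell-like cells, with at least 100 cells in each library. The 3 comparisons were cold with saline, CL with saline and CL with cold. With 1 library per group and no replicates no test was run.

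The genes named were set by a rule fixed in advance, as were the samples' groups, the filters, the markers, the lists and most of the alternatives. In each main class the rule took genes with at least 50 UMIs in the higher library and at least 0.25 of the highest CPM of that gene in any other class of at least 50 cells. It left out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor, sex-linked and unnamed predicted genes. Of the rest it took the 5 highest and 5 lowest against saline, and 3 and 3 for CL against cold, ranked by the interval bound nearer to 0. Up to 4 members of each list with at least 20 UMIs and 15 genes chosen in advance were added. The text gives a selection of these, with priority to genes that differ most. Slc15a2 by class, the genes that define a cluster and the members of the tests in the closing section were chosen after their values were seen.

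The 32 gene lists were fixed in advance, from S-phase, interferon response and thermogenic genes to markers of lymph node, muscle and epithelium. A list's value is the median log2 ratio over members with at least 10 UMIs in the libraries compared, with an interval from 500 redraws of the counts, and members at 0 in a library took a floor of 3 counts. Its place among 10000 random lists matched on expression was computed as a description and is not printed. Clec7a was not analysed here, and 11 of the 12 type 2 response genes were used. Genes with near copies, such as Bcl2a1b and Bcl2a1d, the Cd209, Ifit and H2 families and some chemokines, share reads, so that the split among copies is uncertain.

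Alternatives for shares were a minimum of 200 or 1000 genes, at most 5% mitochondrial UMIs, doublets kept, resolutions of 0.5 and 2, each library clustered alone, cells thinned to 1000 UMIs (52, 23 and 87 shallower cells left out) and no cell cycle genes in the clustering. Alternatives for genes and lists were totals without mitochondrial and ribosomal genes, ratios centred on the median gene, the mean of each cell's own CPM, doublets kept, cells with a UMI of Mki67 or Top2a left out, and list minimums of 1 and 50 UMIs. With doublets kept, all cells were clustered and named anew, so the members of a class could change as well. Values within the largest saline cluster of a class alone were added after seeing the data. This setting keeps the treated cells that grouped with saline cells, so it selects on expression as well as removing the mix of clusters.

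The procedure was tested on simulated data with the depth of each class and library, in which 200 genes were made to differ. Counts were drawn from Poisson distributions, the model behind the intervals, with no spread between cells, animals or preparations. Coverage near 95% was thus built in, so the test checks the computation and not how the intervals hold in real libraries. Intervals of the other genes held 0 in 95.5% to 96.8% of cases, and those of the 200 genes held the true ratio in 93.0% to 98.5%. Genes made 4-fold different had an interval apart from 0 in 100% of cases, those made 2-fold different in 83.1% to 98.5% and those made 1.5-fold different in 39.4% to 79.0%. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.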

Results

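Single-cell RNA libraries were made from the stromal vascular fraction (SVF, the cells of fat other than intact adipocytes) of inguinal white fat of C57BL/6 mice. The treatments were saline, cold (4 C for 3 days) and CL, the labels' short name for a selective agonist of the β3-adrenergic receptor (1 mg/kg, 3 days), with 1 library each. The number of animals behind a library, and whether the cold mice were injected, were not given in the sources used here. The saline, cold and CL libraries held 7674, 5050 and 7943 barcodes, with totals of 25875379, 19899223 and 29323106 UMIs (unique molecular identifiers, each marking a captured RNA molecule). After filtering, 6175, 3858 and 6628 cells remained, with medians of 3209, 3623 and 3835.5 UMIs per cell.

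Clusters were given a cell class by fixed marker genes, and each class is called by its nearest type, as in "T cell-like". Levels are CPM (counts per 1000000) of the UMIs summed over the cells of a class, and ratios between libraries are log2 values, above 0 where the library named before "over" was higher. With 1 library per group there was no spread between animals to compare against, so no p-value was computed and a difference between libraries cannot be separated from a difference between animals or preparations. Intervals in parentheses are 95% intervals that cover counting error only. They are exact for shares, CPM and gene ratios, normal approximations for ratios of shares, and from redrawn counts for list medians. For CPM, gene ratios and list medians they take UMIs as independent, so they are too narrow where few cells hold most UMIs of a gene. UMIs remove PCR copies, but differences in capture between libraries remain in every ratio.

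The comparison of cold with saline asked which cells and genes of inguinal SVF differed after 3 days at 4 C. Monocyte/macrophage-like cells made up a smaller share of the immune-like cells in the cold library, 14.1% (12.9 to 15.5) against 26.9% (25.6 to 28.2), a log2 ratio of -0.93 (-1.07 to -0.78). B cell-like cells made up a larger share, 48.2% against 36.5% and a ratio of 0.40 (0.32 to 0.48), and T cell-like cells a nearly equal one, 11.1% against 11.0%. Within fat progenitors and macrophages, genes induced by interferon were lower in the cold library, and the cold-inducible RNA-binding gene Cirbp was higher in all 4 main classes. Ucp1, the uncoupling protein of thermogenic fat, was higher in the cold library over all cells, at 148 against 8 UMIs and a log2 ratio of 4.60 (3.58 to 5.84). Of the 148 UMIs, 88 were in endothelial-like cells, where 3 cells held 47, so this interval is too narrow.

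Dendritic cell-like cells took 16.9% of the cold and 20.4% of the saline immune-like cells, a log2 ratio of -0.27 (-0.41 to -0.13). NK cell-like cells took 2.91% and 1.31%, a ratio of 1.16 (0.68 to 1.63) from 84 and 58 cells. Among non-immune-like cells, adipose stem and progenitor cell-like (ASPC-like) cells took 61.0% (57.8 to 64.1) in the cold and 70.1% (67.8 to 72.2) in the saline library. Endothelial-like cells took 21.8% against 14.97%, a ratio of 0.54 (0.30 to 0.78). Schwann-like cells took 6.67% against 3.45%, a ratio of 0.95 (0.46 to 1.44). The share of B cell-like cells turned to a log2 ratio of -0.68 with at most 5% mitochondrial UMIs, and that of dendritic cell-like cells to 0.05. The share of monocyte/macrophage-like cells lay between -1.75 and -0.58 under the alternatives.

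**Figure D1:**
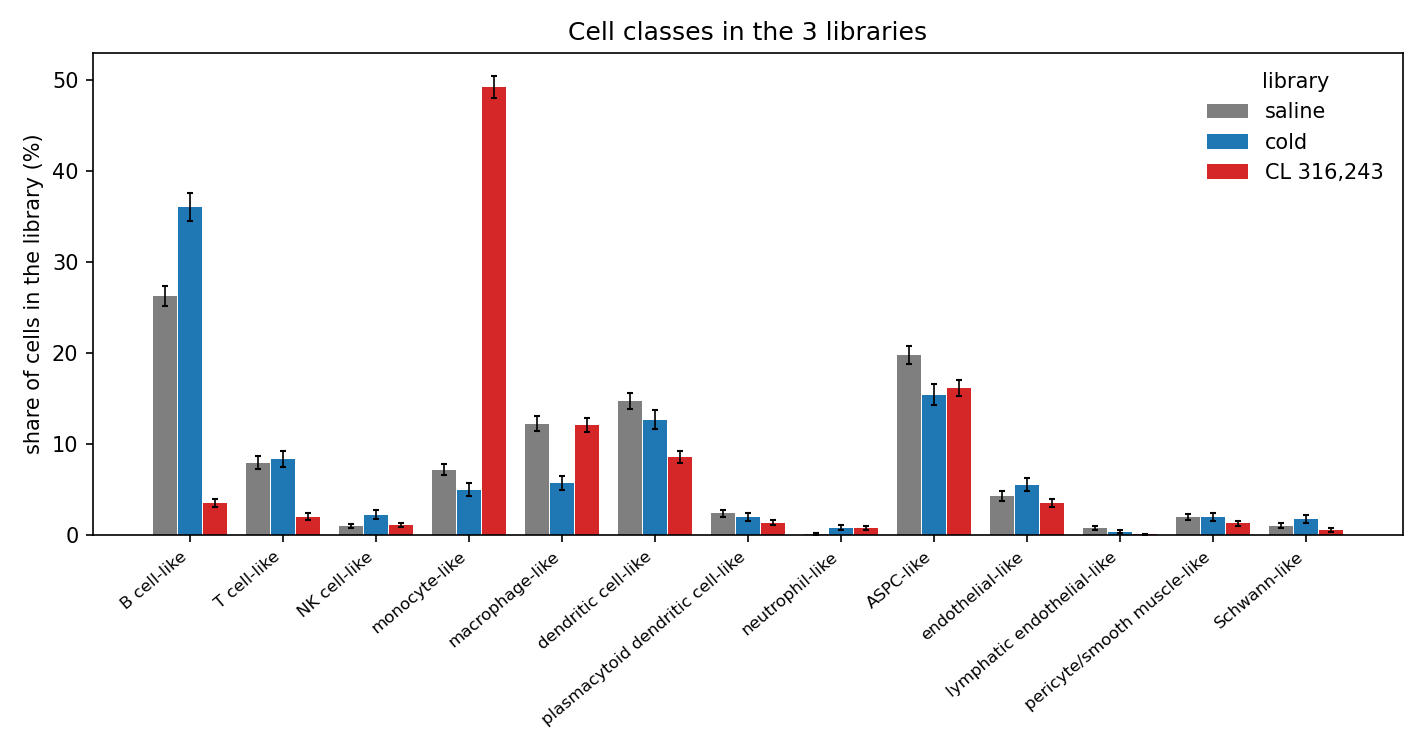
Shares of cell classes, in percent of all cells of a library (vertical axis), in the saline, cold and CL libraries (colours). Bars are shares of 1 library each and error bars are exact 95% Clopper-Pearson intervals. Monocyte-like cells stood at 7.14%, 4.925% and 49.2% and B cell-like cells at 26.3%, 36.0% and 3.50% of all cells.

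In ASPC-like cells (594 cold, 1217 saline), 14 of 15 measured interferon response genes were lower in the cold library, with a median log2 ratio of -1.07 (-1.23 to -0.84). Ifit1 (an interferon-induced RNA-binding protein; ENSMUSG00000034459; chromosome 19, 34640871 to 34650009) was at 6.18 against 43.5 CPM, a ratio of -2.81 (-3.44 to -2.25). Irf7, a transcription factor of the interferon pathway, was at -2.34 (-2.69 to -2.00), Ifit3 at -1.67 (-2.21 to -1.16) and Rsad2, the antiviral enzyme viperin, at -1.52 (-2.61 to -0.58). Within cluster 4, the largest of the class, these 4 genes were at -1.41, -1.35, -0.31 and -0.35, and the median at -0.35. Of the 11 glucocorticoid response genes, 10 were lower, with a median of -0.60 (-0.71 to -0.45). They included the metallothioneins Mt1 at -1.29 (-1.35 to -1.23) and Mt2 at -1.29 (-1.37 to -1.21), and the clock gene Per1 at -0.87 (-1.21 to -0.53). Irs2, an adaptor of the insulin receptor, was at -1.39 (-1.56 to -1.21). Higher genes included Vwc2, a secreted modulator of BMP signalling, at 2.91 (2.11 to 3.80), and Myoc (the secreted glycoprotein myocilin; ENSMUSG00000026697; chromosome 1, 162639155 to 162649693), at 159 against 38.2 CPM and 2.06 (1.86 to 2.26). Tcta was at 1.63 (1.10 to 2.17) and Igfbp3, a binding protein of insulin-like growth factors, at 1.25 (1.08 to 1.42).

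Both cold-inducible RNA-binding genes were higher in cold ASPC-like cells, with a median of 1.02 (0.88 to 1.15). Cirbp (chromosome 10, 80165985 to 80172786) was at 67.6 against 26.4 CPM, a ratio of 1.36 (1.09 to 1.62), and Rbm3 at 0.68 (0.58 to 0.77). Of the committed preadipocyte genes, 8 of 9 were higher, with a median of 0.31 (0.24 to 0.45), among them the adhesion gene Icam1 at 0.83 (0.61 to 1.06) and the apolipoprotein Apoe at 0.63 (0.55 to 0.70). Of the adipocyte and adipogenic genes, 11 of 15 were higher, with a median of 0.31 (0.08 to 0.39). The adipogenic regulator Pparg was at 0.60 (0.17 to 1.04) and the perilipin Plin4 at -0.67 (-1.08 to -0.27). The F3 stromal genes had 7 of 8 higher and a median of 0.43 (0.39 to 0.56). Within cluster 4 alone the F3 list turned to -0.22, Pparg to -0.53, Plin4 to 0.05 and Apoe to -0.12, and the committed preadipocyte and adipocyte medians were 0.01 and 0.06. The stromal cytokine genes split 8 higher to 7 lower, with a median of 0.02 (-0.47 to 0.15). Among the latter, the interleukin Il6 was at -1.27 (-1.44 to -1.09) and the chemokine Ccl7 at -1.11 (-1.24 to -0.98), against -0.47 and -0.08 within cluster 4. Medians of the extracellular matrix genes, -0.15 (-0.18 to -0.09), and Dpp4 interstitial progenitor genes, -0.13 (-0.22 to 0.02), lay closer to 0, as did those of the endoplasmic reticulum and integrated stress genes, -0.02 (-0.10 to 0.19). Postn, the matrix protein periostin, was at -0.64 (-0.73 to -0.55) and the serine biosynthesis gene Phgdh at 0.82 (0.49 to 1.14).

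The thermogenic list had 5 measured members in ASPC-like cells, with 2 higher and a median of -0.33 (-0.60 to 0.12). Ebf2, a regulator of beige fat identity, was at -0.33 (-0.44 to -0.23), and Ucp1 had 3 against 0 UMIs. Proliferation genes showed no common direction, with medians of 0.08 (-0.19 to 0.25) for the S-phase and -0.47 (-0.81 to 0.19) for the G2/M genes. Top2a, a topoisomerase of dividing cells, was at -0.84 (-1.72 to -0.03) and Mki67 at -0.53 (-1.47 to 0.33). The progenitor marker Pdgfra was at 0.12 (0.02 to 0.21), Gpnmb at 0.99 (0.85 to 1.13), the alarmin Il33 at -0.52 (-0.80 to -0.24) and the monocyte chemoattractant Ccl2 at 0.10 (-0.01 to 0.21). Cluster 4 held 55.1% of the cold and 54.6% of the saline ASPC-like cells, and cluster 13 held 39 saline cells and no cold cell. Lcn2 and Saa3 had log2 ratios of -2.80 (-4.29 to -1.61) and -5.27 (-6.59 to -4.21) over the class, and Lcn2 is among the genes that define cluster 13. Within cluster 4 alone Arc, an early-response gene, turned from -1.79 to 0.37 and Top2a to 0.05.

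In macrophage-like cells (218 cold, 751 saline), 15 of 16 interferon response genes were lower in the cold library, with a median of -1.40 (-1.63 to -1.09). Cxcl10, a chemoattractant of T cells, was at 31.4 against 198 CPM, a ratio of -2.65 (-3.24 to -2.12), and Irf7 at -2.51 (-3.12 to -1.94). Cxcl9, an interferon-induced chemokine outside the list, went the other way, at 162 against 62.7 CPM. Monocyte genes were lower in 9 of 10 cases, with a median of -1.72 (-2.61 to -1.33), among them Ly6c2, a surface protein of inflammatory monocytes, at -3.90 (-6.20 to -2.32) and Plac8 at -3.42 (-4.75 to -2.35). Inflammatory cytokine genes were lower in 11 of 13, with a median of -0.83 (-1.05 to -0.49). The interleukin Il1b was at -1.87 (-2.56 to -1.25), the neutrophil chemoattractant Cxcl1 at -1.59 (-2.18 to -1.05) and the B cell chemoattractant Cxcl13 at -3.03 (-4.68 to -1.76). Lipid-associated macrophage genes were higher in 15 of 18 cases, with a median of 0.61 (0.55 to 0.82). The lipid receptor Trem2 was at 284 against 105 CPM and 1.44 (1.19 to 1.69), and Gpnmb, a glycoprotein of lysosomes, at 1.68 (1.20 to 2.16). The peptide transporter Slc15a2 was at 3.17 (2.37 to 4.04) and the actin crosslinker Actn1 at 1.82 (1.33 to 2.33).

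Resident perivascular macrophage genes were higher in 10 of 14 cases in the cold macrophage-like cells, with a median of 0.12 (0.04 to 0.19). The selenium carrier Sepp1 was at 0.47 (0.43 to 0.52) and the hyaluronan receptor Lyve1 at -0.26 (-0.41 to -0.11). Type 2 response genes had 7 of 9 lower and a median of -0.30 (-0.71 to -0.17), with Ear2 at -0.87 (-1.34 to -0.43). MHC class II genes had a median of -0.13 (-0.20 to -0.08), with H2-Aa at -0.13 (-0.20 to -0.06). Endoplasmic reticulum and integrated stress genes stood at -0.12 (-0.28 to 0.01), S-phase genes at -0.21 (-0.53 to 0.27) and G2/M genes at 0.35 (-0.61 to 0.92). All 9 heat shock genes were lower, with a median of -0.30 (-0.43 to -0.20), and glucocorticoid response genes stood at -0.40 (-1.02 to -0.24), Mt2 among them at -2.95 (-3.70 to -2.29). Immediate early genes were at -0.14 (-0.20 to -0.07) and the cold-inducible pair at 0.64 (0.39 to 0.88). Cluster 7 held 70.6% of the cold and 70.6% of the saline macrophage-like cells, cluster 19 held 29.4% and 18.1%, and cluster 10 held 85 saline cells and no cold cell. Genes that define cluster 19 went both ways in the cold class, with Marco at 2.77, Mmp12 at 2.06 and Cd209b at 1.49, but Lyz1 at -2.55 and Ear2 at -0.87. Lyz1 also helps to define cluster 10, as does Saa3, which had 2 against 1290 UMIs. Within cluster 7 alone, Marco stood at 0.67, Cd209b at -0.15, Lyz1 at 0.31, Ly6c2 at -0.18, Plac8 at -2.33, Il1b at -1.18 and H2-Aa at 0.03. Medians there were -0.95 for the interferon, -0.90 for the monocyte, -0.02 for the type 2, -1.14 for the glucocorticoid response and 0.03 for the MHC class II genes. With doublets kept, Lyve1 turned to 0.10 and the immediate early median to 0.02.

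In endothelial-like cells (212 cold, 260 saline), all 13 immediate early genes were lower in the cold library, with a median of -1.39 (-1.51 to -1.22), and so were all 9 heat shock genes, with a median of -1.24 (-1.38 to -0.80). The stress-induced transcription factor Atf3 (ENSMUSG00000026628; chromosome 1, 191170296 to 191218039) was at 82.4 against 695 CPM, a ratio of -3.08 (-3.47 to -2.70). Csrnp1 was at -2.76 (-3.50 to -2.08), the kinase Plk3 at -2.53 (-3.32 to -1.81), Tmem252 at -2.48 (-3.30 to -1.74) and the chaperone Hspa1a at -2.15 (-2.49 to -1.82). Glucocorticoid response genes had 9 of 11 lower and a median of -0.94 (-1.23 to -0.46), including the cell cycle inhibitor Cdkn1a at -2.22 (-2.45 to -1.99) and Mt1 at -3.47 (-4.29 to -2.75). Ucp1 (ENSMUSG00000031710; chromosome 8, 83290352 to 83298452) had 88 against 1 UMIs, 110.0 against 1.43 CPM and a log2 ratio of 6.27 (3.75 to 11.59). In the cold library Ucp1 was at 18.3 CPM in pericyte/smooth muscle-like, 4.78 in B cell-like and 0.687 in ASPC-like cells. Of the endothelial-like cells 3 held 47 of the 88 UMIs, and 1 of 65 Schwann-like cells held all 7 UMIs of that class. Cidea, a lipid droplet protein of thermogenic fat, had 13 against 0 UMIs in endothelial-like cells, which is at least 3.79-fold. The 3 cells with most Ucp1 held 8 of these 13 UMIs. The xenobiotic-metabolising enzyme Cyp1a1 was at 2.54 (1.66 to 3.56), the guidance ligand Slit3 at 1.83 (1.09 to 2.63), the creatine kinase Ckb at 1.49 (0.98 to 2.04) and the chemokine Cxcl12 at 1.15 (0.99 to 1.30).

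Capillary lipid handling genes were higher in 9 of 11 cases in cold endothelial-like cells, with a median of 0.58 (0.46 to 0.72). Gpihbp1, which anchors lipoprotein lipase on capillaries, was at 1.03 (0.91 to 1.14) and Fabp5, a fatty acid binding protein, at 0.79 (0.67 to 0.92). All 6 measured endothelial adhesion genes were lower, with a median of -1.24 (-1.96 to -0.90), among them Vcam1 at -2.23 (-2.99 to -1.53). Cluster 28 held 6.60% of the cold and 12.3% of the saline cells, and Selp, which helps to define it, turned from -1.44 to 1.68 within cluster 12, the largest cluster of the class. Angiogenic endothelial genes had a median of 0.11 (-0.04 to 0.35), with the growth factor receptor Kdr at 0.96 (0.81 to 1.12). Interferon response genes had a median of -0.38 (-0.87 to -0.07), S-phase genes one of 0.22 (-0.20 to 0.59) and the cold-inducible pair one of 0.69 (0.41 to 1.01), and no G2/M gene reached 10 UMIs.

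In T cell-like cells (319 cold, 488 saline), where the median over all genes was 0.10, proliferation genes were higher in the cold library. All 16 S-phase genes had a median of 0.62 (0.52 to 0.82) and all 16 G2/M genes one of 0.71 (0.48 to 0.90). The cyclin Ccnb2 was at 1.74 (1.19 to 2.33), the thymidylate synthase Tyms at 1.32 (0.89 to 1.75) and Top2a at 0.40 (0.19 to 0.61), while Mki67 stood at 0.18 (0.00 to 0.36). Without cells with a Mki67 or Top2a UMI, Tyms turned to -0.49. Within cluster 5, the largest of the class, Tyms was at 0.42, Top2a turned to -0.04 and Mki67 to -0.02, with list medians of 0.41 and 1.04. The cycling cluster 24 held 15.7% of the cold and 6.97% of the saline T cell-like cells. Effector and cytotoxic lymphocyte genes were higher in 5 of 7 cases, with a median of 0.75 (0.48 to 0.89), including interferon gamma, Ifng, at 1.66 (1.21 to 2.14) and the chemokine receptor Cxcr3 at 1.66 (1.02 to 2.35). All 8 naive lymphocyte genes were lower, with a median of -0.57 (-0.70 to -0.47), among them Klf2, a regulator of lymphocyte exit from tissue, at -1.30 (-1.51 to -1.09). Bcl2a1d at 1.88 (1.30 to 2.51) and Bcl2a1b at 1.41 (1.18 to 1.63) are survival genes so alike that reads can be counted to the other. Slc15a2 was at 4.84 (3.25 to 7.14) from 98 against 3 UMIs. Sox4 was at -2.19 (-2.94 to -1.50), Dapl1 at -2.09 (-2.77 to -1.45), Pik3ip1, an inhibitor of PI3 kinase, at -2.07 (-2.89 to -1.32), and the glucocorticoid-induced Tsc22d3 at -1.47 (-1.84 to -1.11).

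Heat shock genes were lower in 8 of 9 cases in cold T cell-like cells, with a median of -0.84 (-1.13 to -0.54) and Hsph1 at -1.34 (-1.65 to -1.03). Glucocorticoid response genes had a median of -0.42 (-0.76 to -0.11), immediate early genes one of -0.20 (-0.30 to -0.03) (0.06 in cluster 5), interferon response genes one of 0.20 (-0.19 to 0.52) and the cold-inducible pair one of 0.67 (0.45 to 0.88). Regulatory and type 2 lymphocyte genes stood at 0.02 (-0.12 to 0.12), with Il13 at 10 against 2 UMIs and Il5 at 1 against 5 UMIs. Over all cells the thermogenic genes had a median of -0.04 (-0.30 to 0.25) and the adipocyte and adipogenic genes one of 0.20 (0.08 to 0.26), with Cidea at 2.39 (0.93 to 4.16) and Adipoq, the adipocyte hormone adiponectin, at -0.43 (-1.08 to 0.20). Markers of other material stood at -0.09 (-0.18 to 0.07) for lymph node stromal and follicular genes, -0.09 (-0.12 to 0.03) for erythroid, -1.52 (-2.38 to -0.55) for epithelial, 0.89 (0.09 to 1.40) for skeletal muscle and -0.03 (-0.12 to 0.10) for sex-linked genes. The epithelial median rested on keratins and Wfdc18 with at most 8 cold UMIs each; with at least 50 UMIs per member it turned to 0.34, and Epcam was at 0.49 (0.18 to 0.80).

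The comparison of CL with saline asked which cells and genes differed after 3 days of β3-adrenergic stimulation. Monocyte/macrophage-like cells made up 78.1% (76.98 to 79.2) of the immune-like cells in the CL library and 26.9% (25.6 to 28.2) in the saline library, a log2 ratio of 1.54 (1.47 to 1.61). B cell-like cells made up 4.46% (3.92 to 5.06) against 36.5% (35.1 to 38.0), an 8.18-fold lower share. In all 4 main classes interferon response genes were higher, and in ASPC-like cells so were proliferation genes. Macrophage-like cells were mostly of a cluster with high Saa3, an acute-phase serum amyloid.

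Monocyte-like cells alone took 62.8% (61.4 to 64.1) of the CL and 9.94% (9.07 to 10.9) of the saline immune-like cells, and macrophage-like cells 15.4% and 16.9%. T cell-like cells took 2.50% against 11.0%, a ratio of -2.14 (-2.41 to -1.86), and dendritic cell-like cells 10.9% against 20.4%, a ratio of -0.91 (-1.05 to -0.77). With so many monocyte-like cells in the CL library, shares of the other immune-like classes are lowered by dilution as well. Per endothelial-like cell there was 1.00 B cell-like cell (0.83 to 1.20) in the CL library and 6.23 (5.47 to 7.13) in the saline library. Dendritic cell-like cells stood at 2.44 (2.09 to 2.85) and 3.48 (3.03 to 4.02). Macrophage-like cells numbered 799 and 751, beside 232 and 260 endothelial-like cells. ASPC-like cells took 74.8% against 70.1% of the non-immune-like cells and endothelial-like cells 16.2% against 14.97%. Lymphatic endothelial-like cells numbered 2 and 42. With at most 5% mitochondrial UMIs the ASPC-like ratio turned from 0.09 to -0.04. With each library clustered alone the monocyte/macrophage-like ratio was 0.28, since many CL monocyte cells then stayed unnamed.

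In ASPC-like cells (1069 CL, 1217 saline), all 16 interferon response genes were higher in the CL library, with a median of 2.96 (2.85 to 3.07). Isg15, a ubiquitin-like antiviral protein, was at 843 against 63.8 CPM, a ratio of 3.73 (3.59 to 3.86), Ifi44 at 5.03 (3.96 to 6.36) and Rsad2 at 4.04 (3.65 to 4.46), against 2.04, 1.85 and 1.64 within cluster 4. Cxcl9 (an interferon-induced chemoattractant of T cells; ENSMUSG00000029417; chromosome 5, 92321347 to 92328079) was at 846 against 63.1 CPM, a ratio of 3.74 (3.61 to 3.88). Of the stromal cytokine genes, 13 of 15 were higher, with a median of 0.90 (0.83 to 1.01), including Saa3 at 5.04 (4.91 to 5.18), Cxcl10 at 1.59 (1.51 to 1.67) and Ccl2 at 1.34 (1.26 to 1.42). All 16 G2/M genes were higher, with a median of 1.52 (1.37 to 2.03), and 15 of 16 S-phase genes, with a median of 1.10 (0.89 to 1.33). Mki67 was at 1.43 (0.90 to 1.99) and Top2a at 1.40 (0.93 to 1.88). The protease inhibitor gene Serpinb2 had 68 against 0 UMIs, which is at least 24.6-fold.

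Several genes of the matrix were lower over the CL ASPC-like class. Comp, the cartilage oligomeric matrix protein, was at -3.25 (-4.75 to -2.05), the laminin Lamc3 at -2.53 (-3.42 to -1.73), the microfibril protein Mfap4 at -2.24 (-2.79 to -1.73) and the matrix protein Cilp, which helps to define cluster 14, at -1.80 (-2.10 to -1.50). Tmem132c was at -2.53 (-3.54 to -1.64). Of the extracellular matrix genes, 17 of 20 were lower, with a median of -0.19 (-0.24 to -0.17), fibronectin, Fn1, among them at -0.87 (-0.90 to -0.84). Within cluster 4 alone this median turned to 0.17, with Col4a1 at 0.37, Lox at 0.26, Fn1 at -0.27, Cilp at -1.12 and Tmem132c at -1.67. Dpp4 interstitial progenitor genes were lower in 9 of 10 cases, with a median of -0.34 (-0.39 to -0.29) and Dact2 at -1.20 (-1.51 to -0.90). All 11 glucocorticoid response genes were lower, with a median of -0.61 (-0.77 to -0.44), and 9 of 13 immediate early genes, with a median of -0.54 (-0.56 to -0.48) that turned to 0.12 within cluster 4. Sgk1, a kinase of the glucocorticoid response, was at -0.96 (-1.12 to -0.81) and Junb at -0.77 (-0.81 to -0.73), against -0.24 and -0.26 in cluster 4, where the glucocorticoid median was -0.24.

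Adipocyte and adipogenic genes had a median of -0.19 (-0.35 to 0.10) in these cells, committed preadipocyte genes 0.07 (-0.06 to 0.19) and F3 stromal genes -0.03 (-0.16 to 0.06). The carbonic anhydrase Car3 was at 1.31 (1.07 to 1.55), Plin4 at -1.44 (-1.86 to -1.03) and Bst1 at 3.40 (1.93 to 5.35). Thermogenic genes had a median of 0.28 (-0.41 to 0.66), with Cox8b, a mitochondrial subunit of thermogenic fat, at -1.88 (-3.12 to -0.80) and Ucp1 at 0 against 0 UMIs. Endoplasmic reticulum and integrated stress genes had a median of 0.18 (0.14 to 0.27), with Asns at 1.01 (0.64 to 1.38), heat shock genes -0.10 (-0.19 to 0.05) and the cold-inducible pair 0.41 (0.27 to 0.56). Pdgfra was at -0.50 (-0.59 to -0.41). Cluster 13 held 38.9% of the CL and 3.20% of the saline ASPC-like cells, and cluster 4 held 20.5% and 54.6%. Genes that define cluster 13 were higher over the class, as the iron-scavenging lipocalin Lcn2 at 383 against 9.57 CPM and 5.32, the neutrophil chemoattractant Cxcl5 at 5.84 and the protease inhibitor Timp1 at 3.22. Within cluster 4 alone Lcn2 was at 1.03, Cxcl9 at 1.14, Saa3 at 1.55, Cxcl10 at 0.12, Ccl2 at 0.54, Timp1 at 1.09, Car3 at 0.21 and Asns at 0.23. There the stromal cytokine median was 0.53 and the interferon median 1.65, while Il33 turned from 1.28 to -0.45 and Gpnmb from -0.95 to 0.85.

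**Figure D2:**
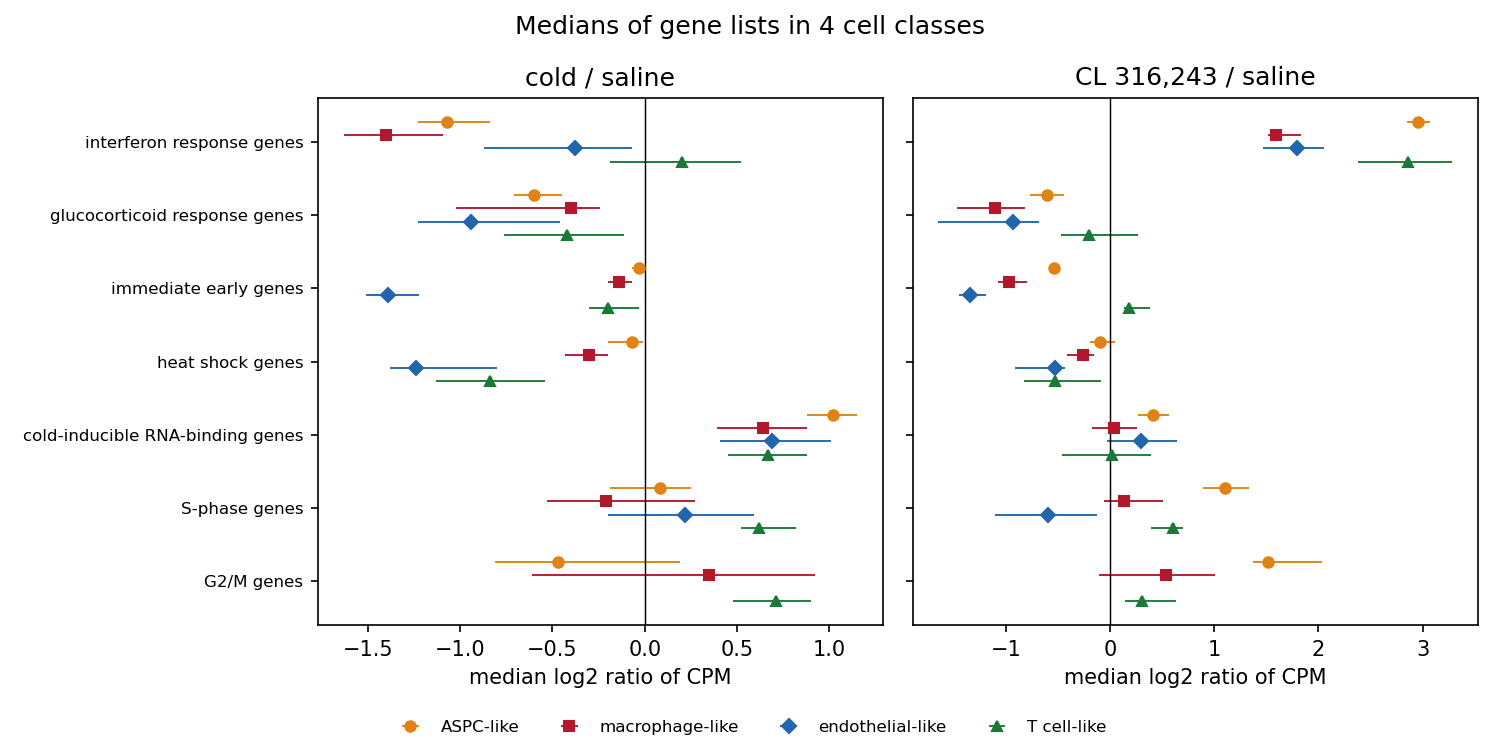
Median log2 ratio of CPM (horizontal axis) of 7 fixed gene lists in 4 cell classes (symbols), for cold over saline on the left and CL over saline on the right; error bars are 95% counting intervals from redrawn counts. Interferon response genes in ASPC-like cells stood at -1.07 in the cold and 2.96 in the CL comparison, and the cold-inducible pair at 1.02 and 0.41.

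In macrophage-like cells (799 CL, 751 saline), cluster 10 held 83.2% of the CL and 11.3% of the saline cells, and cluster 7 held 11.9% and 70.6%. Class values hence compare mostly cluster 10 with cluster 7, and the median over all genes was 0.13. Monocyte genes were higher in 9 of 10 cases, with a median of 2.28 (2.05 to 2.52), including Ly6c2 at 3.05 (2.77 to 3.33) and the haemoglobin scavenger haptoglobin, Hp, at 4.15 (3.45 to 4.94). Interferon response genes were higher in 15 of 16, with a median of 1.59 (1.52 to 1.83) and Irf7 at 729 against 161 CPM, a ratio of 2.18 (2.03 to 2.34). Cxcl10 was lower, at 148 against 198 CPM, as was Cxcl9, outside the list, at 24.0 against 62.7 CPM. The chemokine Ccl5 was at 3.76 (3.55 to 3.98), Lcn2 at 5.54 (4.86 to 6.33) and Wfdc21 at 6.54 (4.98 to 8.82) from 366 against 3 UMIs. The uridine phosphorylase Upp1 was at 6.19 (3.68 to 11.51) from 96 against 1 UMIs. Saa3 (ENSMUSG00000040026; chromosome 7, 46711998 to 46715700), which leads the genes that define cluster 10, was at 14100 against 522 CPM over the class. Within cluster 7 alone Hp was at 1.85, Irf7 at 1.33, Ccl5 at 0.13 and Lcn2 at 0.68, and the monocyte median was 2.04.

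All 14 resident perivascular macrophage genes were lower in the CL class, with a median of -1.42 (-1.47 to -1.38), among them the scavenger receptor Cd163 at -2.57 and Lyve1 at -1.74. Type 2 response genes had a median of -1.03 (-1.64 to -0.51), with the secreted resistin-like Retnla at -2.68, and all 7 MHC class II genes were lower, with a median of -1.18 (-1.24 to -1.06). Several of these define cluster 7. Within cluster 7 alone the resident list turned to 0.27 and the type 2 list to 0.04, and the MHC class II median was -0.37. There Saa3 was at 2.02, Cd163 at -0.30, Retnla at -0.16, Lyve1 at 0.50 and the interferon median at 0.68. Among genes of cluster 19, the lectin Cd209b was at -3.53 and the phospholipase Pla2g2d at -3.71 over the class. Cd209d was at -3.28 (-3.54 to -3.02), and the nuclease Dnase1l3 turned from -3.67 to 0.68 in cluster 7, where Cd209b was at -0.78, Pla2g2d at -0.80 and Cd209d at -0.82.

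Lipid-associated macrophage genes had a median of 0.16 (0.06 to 0.27), which turned to -0.34 with doublets kept, with Spp1, the secreted protein osteopontin, at 2.32 (1.72 to 2.97) and Trem2 at 0.00 (-0.23 to 0.24). Inflammatory cytokine genes stood at 0.12 (-0.03 to 0.34), with Il1b at 1.28 (1.06 to 1.51) and the NF-kB regulator Nfkbiz at -1.18 (-1.33 to -1.03). Glucocorticoid response genes were lower in 10 of 11 cases, with a median of -1.11 (-1.47 to -0.82) and Klf9 at -3.20 (-3.69 to -2.74). Immediate early genes had a median of -0.97 (-1.08 to -0.80), with Egr1 at -1.68 (-1.77 to -1.58), and heat shock genes one of -0.26 (-0.41 to -0.16), which turned to 0.16 within cluster 7. There the immediate early median was -0.54, Egr1 at -0.16, Klf9 at -1.95 and Trem2 at 1.16. S-phase genes stood at 0.13 (-0.06 to 0.51), G2/M genes at 0.54 (-0.11 to 1.01), stress genes of the endoplasmic reticulum at -0.04 (-0.17 to 0.01) and the cold-inducible pair at 0.04 (-0.17 to 0.26).

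In endothelial-like cells (232 CL, 260 saline), 13 of 14 interferon response genes were higher in the CL library, with a median of 1.79 (1.47 to 2.05). Irf7 (ENSMUSG00000025498; chromosome 7, 141262706 to 141266481) was at 350 against 37.1 CPM, a ratio of 3.24 (2.64 to 3.89), Ifi44 at 3.19 (2.12 to 4.47), Ifit1 at 2.27 (1.54 to 3.06) and Rsad2 at 1.94 (1.53 to 2.36). Cxcl12 was at 1.59 (1.44 to 1.75). All 13 immediate early genes were lower, with a median of -1.35 (-1.45 to -1.19) and Atf3 at -2.92 (-3.38 to -2.50), and glucocorticoid response genes stood at -0.93 (-1.65 to -0.68), with Cdkn1a at -1.80 (-2.04 to -1.56). Heat shock genes had a median of -0.53 (-0.91 to -0.43). The membrane protein gene Emp2 was at -3.21 (-4.70 to -2.01) and Gkn3 at -2.73 (-3.69 to -1.90). All 6 measured adhesion genes were lower, with a median of -1.79 (-2.66 to -1.41), which was -0.74 within cluster 12. Cluster 28, which Selp and Cytl1 help to define, held 2.16% of the CL and 12.3% of the saline cells. Over the class Selp was at -2.96 and Cytl1 at -3.08, and in cluster 12 Selp was at 0.14.

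Angiogenic endothelial genes were higher in 8 of 9 cases in CL endothelial-like cells, with a median of 0.46 (0.33 to 0.69) and Kdr at 1.15 (0.98 to 1.31). Capillary lipid handling genes were higher in 10 of 11, with a median of 0.28 (0.18 to 0.42) and Gpihbp1 at 0.66 (0.53 to 0.79). S-phase genes had a median of -0.60 (-1.11 to -0.13) and the cold-inducible pair one of 0.30 (-0.03 to 0.64). Ucp1 had 5 against 1 UMIs in these cells.

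In T cell-like cells (130 CL, 488 saline), all 14 measured interferon response genes were higher in the CL library, with a median of 2.86 (2.38 to 3.28). Ifi27l2a, an interferon-induced gene, was at 1596 against 359 CPM, a ratio of 2.15 (1.99 to 2.31), the nucleic acid sensor Zbp1 at 2.28 (1.77 to 2.81), the ubiquitin ligase Rnf213 at 1.86 (1.32 to 2.40) and Irf7 at 4.67 (3.77 to 5.72). Effector and cytotoxic lymphocyte genes were higher in 7 of 8 cases, with a median of 1.04 (0.70 to 1.35), including the granzyme Gzmb at 1.17 (0.68 to 1.66) and Ccl5 at 2.17 (1.93 to 2.42). Cdkn1a was at 1.63 (1.19 to 2.06) and Tspo, of the outer mitochondrial membrane, at 1.39 (1.18 to 1.60). All 8 naive lymphocyte genes were lower, with a median of -0.67 (-0.92 to -0.51), among them the transcription factor Lef1 at -1.63 (-2.30 to -1.01). Sox4 was at -3.34 (-5.65 to -1.75), Nsg2 at -1.91 (-2.85 to -1.09), Gdap10 at -2.02 (-3.12 to -1.09) and AI504432 at -1.76 (-2.71 to -0.93). S-phase genes had a median of 0.60 (0.39 to 0.70), G2/M genes 0.31 (0.14 to 0.63), heat shock genes -0.53 (-0.83 to -0.09) and regulatory and type 2 lymphocyte genes 0.00 (-0.22 to 0.18). The cycling cluster 24 held 16.9% of the CL and 6.97% of the saline cells, and within cluster 5 alone the S-phase median was 0.29 and the G2/M median 0.31, with Rrm2 at -0.34. Glucocorticoid response genes stood at -0.20 (-0.47 to 0.27), immediate early genes at 0.18 (0.13 to 0.38) and the cold-inducible pair at 0.02 (-0.46 to 0.39).

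Over all cells the lymph node stromal and follicular genes had a median of -3.29 (-3.61 to -3.03) in CL over saline, with the lymphatic chemokine Ccl21a at 3 against 133 UMIs and Cr2, a complement receptor of B cells, at -3.97 (-4.34 to -3.62). Thermogenic genes had a median of -0.30 (-0.74 to 0.20) and adipocyte and adipogenic genes one of -0.09 (-0.18 to 0.06), with Ucp1 at 1.60 (0.43 to 2.95) and Ccl2 at 1.69 (1.64 to 1.74). The Ucp1 ratio rests on few UMIs, with 8 in the saline library. In the CL library 12 were in 12 of 3262 monocyte-like cells, 5 in endothelial-like and 0 in ASPC-like cells. Free RNA was not excluded. Erythroid genes stood at -0.32 (-0.34 to -0.22), epithelial genes at -2.03 (-2.53 to -1.60), skeletal muscle genes at -0.20 (-0.72 to 0.41) and sex-linked genes at -0.48 (-0.54 to -0.36). The Y-linked Ddx3y was at 83.5 against 129 CPM, with 115 CPM in the cold library, and Xist had between 0 and 3 UMIs in a library. The mix of classes enters this Ddx3y difference, as CL monocyte-like cells stood at 64.3 CPM. In ASPC-like cells Ddx3y was at 114 CPM in the CL, 116 in the cold and 122 in the saline library. In macrophage-like cells it was at 69.0 against 105 CPM in CL and saline, so some classes differed as well.

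The comparison of CL with cold asked where drug stimulation and cold exposure differed. Monocyte/macrophage-like cells took 78.1% of the immune-like cells in the CL and 14.1% in the cold library, a log2 ratio of 2.46 (2.33 to 2.60), and B cell-like cells 4.46% and 48.2%, a ratio of -3.43 (-3.62 to -3.24). Interferon response genes were higher in the CL library in all 4 main classes, with medians of 3.89 (3.70 to 4.54) in ASPC-like, 2.89 (2.72 to 3.24) in macrophage-like, 1.96 (1.75 to 2.41) in endothelial-like and 3.55 (2.67 to 3.88) in T cell-like cells. Cirbp was lower in the CL library, at -1.31 (-1.58 to -1.04) in ASPC-like and -1.52 (-2.00 to -1.04) in macrophage-like cells. Ucp1 in endothelial-like cells was at 5 against 88 UMIs, a ratio of -3.58 (-5.24 to -2.31).

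In ASPC-like cells Ifit1 was at 337 against 6.18 CPM, a ratio of 5.77 (5.22 to 6.37), and Il33 at 1.80 (1.54 to 2.06). Lcn2 was at 8.12 from 2728 against 6 UMIs, and Cxcl5 had 529 against 0 UMIs, at least 108-fold, where both help to define cluster 13, which had no cold cell. Stromal cytokine genes were higher in 13 of 15 cases, with a median of 1.23 (1.11 to 1.31) and Ccl2 at 1.23 (1.14 to 1.33). All 16 S-phase genes had a median of 1.18 (0.93 to 1.40) and all 15 measured G2/M genes one of 2.22 (1.55 to 2.44). Myoc was lower, at -2.64 (-2.89 to -2.40), as were Lamc3 at -3.01 (-3.92 to -2.19), Mlana at -2.84 (-3.83 to -1.95) and Gpnmb at -1.94 (-2.12 to -1.76). All 8 F3 stromal genes were lower, with a median of -0.54 (-0.69 to -0.43), and committed preadipocyte genes had a median of -0.36 (-0.45 to -0.23), with Fabp4 at -1.01 (-1.09 to -0.93). Adipocyte and adipogenic genes had a median of -0.39 (-0.51 to -0.12), Dpp4 interstitial progenitor genes -0.43 (-0.48 to -0.38) and extracellular matrix genes -0.09 (-0.13 to -0.06). Within cluster 4 alone the interferon median was 2.13, but the F3 list turned to 0.09, the committed preadipocyte list to 0.28, the adipocyte list to 0.16 and the extracellular matrix list to 0.32. There Fabp4 turned to 1.12, and Il33 and Ccl2 to -0.05 and -0.05, while Ifit1 was at 3.14, Lcn2 at 3.45, Myoc at -1.91, Gpnmb at -0.79 and the stromal cytokine median at 0.49.

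In macrophage-like cells, where the median over all genes was 0.11, monocyte genes had a median of 4.42 (4.02 to 4.84), with Ly6c2 at 6.95 (5.40 to 9.23) from 1260 against 3 UMIs. Inflammatory cytokine genes were higher in 10 of 13 cases, with a median of 0.85 (0.71 to 1.15) and Il1b at 3.15 (2.56 to 3.82). Irg1, the enzyme that makes itaconate, had 693 against 0 UMIs, at least 67.9-fold, and Lcn2 1041 against 0 UMIs, at least 102-fold. Saa3 had 45781 against 2 UMIs, with no cold cell in cluster 10. All 14 resident perivascular macrophage genes were lower, with a median of -1.52 (-1.62 to -1.45), and all 7 MHC class II genes, with a median of -1.06 (-1.13 to -0.98). Lipid-associated macrophage genes had a median of -0.55 (-0.65 to -0.39), with Trem2 at -1.43 (-1.67 to -1.20) and Gpnmb at -1.26 (-1.68 to -0.84). Dnase1l3 was at -4.32 (-5.13 to -3.59), Cd209d at -3.66 (-3.93 to -3.39) and Cd209b, of cluster 19, at -5.02. Within cluster 7 alone the interferon median was 1.72 and the MHC class II median -0.41, but the resident list turned to 0.08, the lipid-associated list to 0.12 and Dnase1l3 to 0.05. There the monocyte median was 2.94, Ly6c2 at 3.08, Trem2 at -0.11, Cd209d at -1.11 and Cd209b at -0.63.

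In endothelial-like cells Irf7 was at 4.55 (3.71 to 5.52), Ifi44 at 3.39 (2.31 to 4.67) and Ifit1 at 3.08 (2.22 to 4.05) in CL over cold, and the complement factor Cfd at -2.64 (-3.29 to -2.06). Cytl1, of cluster 28, was at -2.27. Immediate early genes, lower than in saline in both libraries, had a median of 0.04 (-0.05 to 0.17), heat shock genes one of 0.37 (0.12 to 0.58) and capillary lipid handling genes one of -0.32 (-0.40 to -0.16). In T cell-like cells Ifi27l2a was at 2.06 (1.91 to 2.21), Zbp1 at 1.96 (1.49 to 2.43) and Rnf213 at 135 against 33.8 CPM, while Tnfsf8, a TNF family ligand, was at -2.22 (-3.00 to -1.54), Nsg2 at -1.97 (-2.91 to -1.16) and Bcl2a1d at -2.09 (-3.25 to -1.12). S-phase genes had a median of -0.10 (-0.29 to 0.02) and naive lymphocyte genes one of -0.09 (-0.38 to 0.11). Over all cells, where the median over all genes was -0.13, lymph node genes had a median of -3.60 (-3.92 to -3.34) and Ucp1 was at -3.00 (-3.63 to -2.41). With each library clustered alone, the T cell-like share of CL over cold turned from -2.15 to 0.60, since the cold T cell cluster then took another name.

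**Figure D3:**
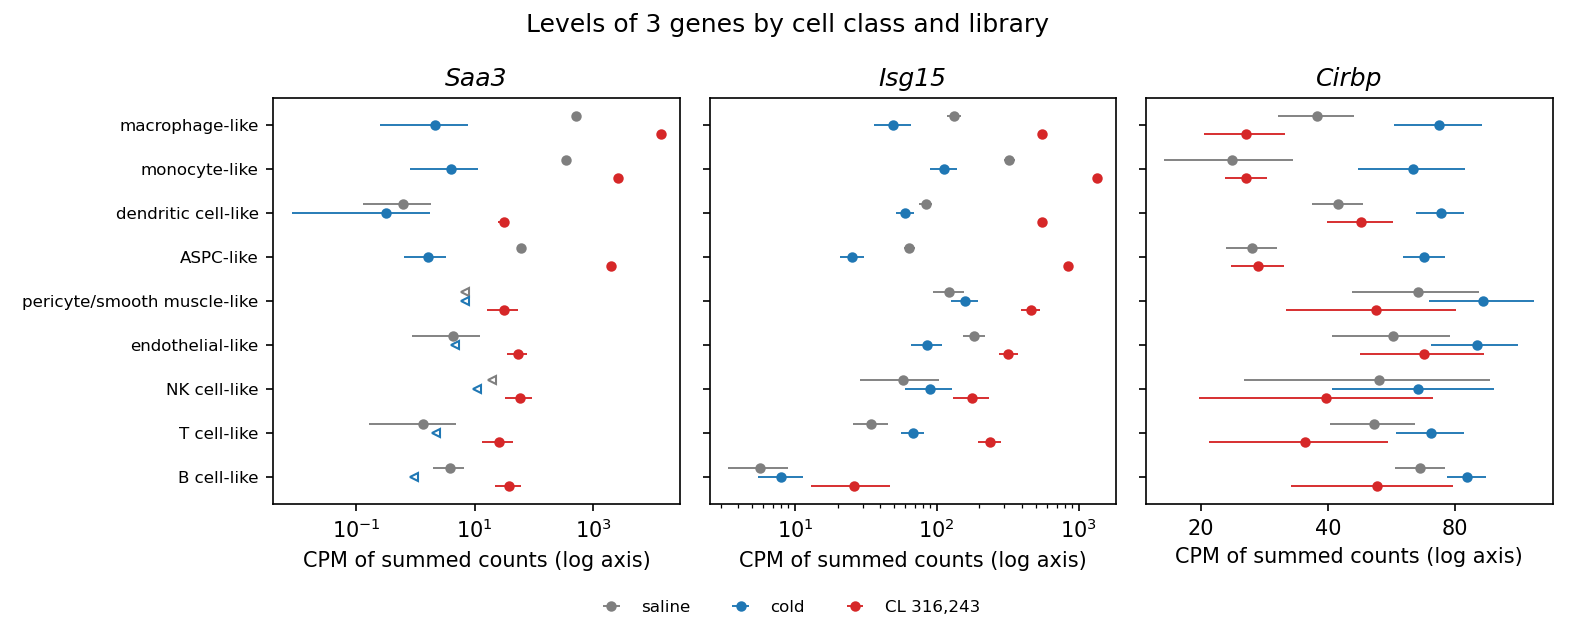
CPM of summed counts (log axis) of Saa3, Isg15 and Cirbp in 9 cell classes of the saline, cold and CL libraries (colours); points are 1 library each, error bars are exact 95% Poisson intervals, and open triangles mark upper limits from 0 UMIs. Isg15 in ASPC-like cells stood at 63.8, 25.4 and 843 CPM and Cirbp at 26.4, 67.6 and 27.3 CPM in the saline, cold and CL libraries.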

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

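All tests in this part were chosen after the results they bear on were seen. Among the barcodes with under 500 genes, which the comparisons leave out, neutrophil markers together stood at 3790 CPM (3670 to 3910) in the CL library, 483 (442 to 526) in the saline and 113 (94.9 to 135) in the cold library. The CL level was above the saline level, which is why it is given here; only neutrophil markers were compared in this way, a choice made after the table of all classes was seen. Among the cells that passed, neutrophil-like cells numbered 49, 3 and 29. No explanation of the neutrophil markers was tested.

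Clusters 2, 10 and 13, which held 45.1% of the CL cells, also held 266 saline cells (4.31%) and 3 cold cells. Reads assigned to the wrong library by index hopping would give these saline cells barcodes of the CL library, and 1 of the 266 had such a barcode (upper limit 2.08%), against 10 of 5909 other saline cells. Cells of the CL sample mixed into the saline sample would carry the CL level of Saa3, and the highest log2 ratio of Saa3 in saline over CL cells of the same cluster was -2.04 over the 3 clusters. The barcodes argue against index hopping. The Saa3 levels argue against all of these saline cells being CL cells. A mix with only some CL cells would also lower the mean, so partial mixing is not excluded. Other genes varied in cluster 13, with Timp1 at -0.39 (-0.57 to -0.22) and Lcn2 at -4.00 (-5.01 to -3.16). Partial mixing, a response to the saline injection or handling, and a difference between animals remain open and were not tested.

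B cell-like and T cell-like cells were fewer per endothelial-like cell in the CL than in the saline library, with a log2 ratio of -2.38 (-2.68 to -2.08), which dilution of all other cells by monocyte/macrophage-like cells would leave near 0. With a minimum of 200 genes the ratio was -2.40 (-2.66 to -2.13), which argues against a loss of shallow lymphocytes to the gene minimum. Less lymph node tissue in the CL sample would lower stromal lymph node genes as well, and Ccl21a and Madcam1 together stood at -4.24 (-6.15 to -2.83) over non-immune-like cells, a value that rests on Ccl21a (2 against 85 UMIs), as Madcam1 had 2 against 3. Ccl21a is also a gene of lymphatic vessels, so a difference in how much of the lymph node was taken may have a part but is not shown. Cxcl13, of the same lymph node list, was higher in CL over all cells (3830 against 2512 UMIs). That count includes immune-like cells, so it does not bear on lymph node stroma alone and cannot decide this. An effect of the drug on lymphocytes remains open and was not tested.

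Ucp1 was found in 29 of the 212 cold endothelial-like cells (13.7%), against 3 of 594 cold ASPC-like cells (0.51%), at median depths of 2939 and 7439.5 UMIs. Free RNA would reach all classes alike, but without the 3 cells with most Ucp1 the log2 ratio of endothelial-like cells over all other classes was 3.92 (3.31 to 4.52). For RNA of beige or brown adipocytes joined to these cells, a first test of 6 adipocyte markers met the bound against it, an upper limit under 1, that had been set before its value was seen: the log2 ratio of cells with a Ucp1 UMI over those without was 0.61 (0.24 to 0.97), but Car3 made up 69 of 82 and 246 of 294 of the UMIs and was at 363 CPM in cells without Ucp1, so that sum says little of adipocytes. The other thermogenic genes, tested only after Cidea and Cox8b had been seen to be higher, gave 1.67 (1.04 to 2.29) from 36 and 62 UMIs, while Adipoq had 1 UMI. The 3 cells with most Ucp1 were kept in this test. They held 8 of the 11 Cidea and 2 of the 7 Cox8b UMIs, so this interval is too narrow. Adipocyte RNA joined to endothelial-like cells and expression of Ucp1 in these cells cannot be told apart here, as the counts are few.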

How the results depend on the processing

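The common doublet limit and the largest clusters alone were chosen after the data were seen, and the other settings before the data were examined. No paired analysis was possible because each group had 1 library. Of 4481 recomputed gene ratios, from 781 combinations of gene, class and comparison, 4353 kept their direction, and 73 reversed; of 1288 list medians 21 reversed, and of 180 shares 4. Other sign changes came from values whose interval held 0, or ended at 0. Among values that kept their direction or lay near 0, 555 recomputed gene ratios, 179 medians and 39 shares left their counting interval. The pooled counts hide differences between settings. Within the largest cluster alone 57 gene ratios reversed, 206 left their interval and 350 stayed in it, and 18, 51 and 71 list medians. With at most 5% mitochondrial UMIs 3 shares reversed, 11 left their interval and 4 stayed. Centring on the median gene reversed 0 gene ratios. Some values have no counterpart under an alternative, where no counts or cells were left. Depth limits all of these results, since differences of 1.5-fold and of 2-fold were missed in part of the simulated cases. Unless a reason is given, the cause was not tested.

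The log2 ratio of monocyte/macrophage-like cells kept its direction in all 10 alternatives, between -1.75 and -0.58 in cold over saline, 0.28 and 1.55 in CL over saline and 1.09 and 2.99 in CL over cold. With a minimum of 200 genes it was -1.17 in cold over saline and 2.71 in CL over cold, and with 1000 genes -1.75, 1.24 in CL over saline and 2.99. At most 5% mitochondrial UMIs gave -0.58, 1.17 and 1.75, and turned the ASPC-like share of CL over saline to -0.04, the B cell-like share of cold over saline to -0.68 and that of dendritic cell-like cells to 0.05. Thinned cells gave 1.30 in CL over saline and 2.29 in CL over cold. Each library clustered alone gave 0.28 and 1.09, since CL monocyte clusters stayed unnamed, and the T cell-like share of CL over cold turned to 0.60, since the cold T cell cluster took another name.

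Within the largest saline cluster of a class alone, cells of the other clusters no longer enter. That cluster held only 20.5% of the CL ASPC-like and 11.9% of the CL macrophage-like cells. Clusters were made from the same expression, so this keeps treated cells that grouped with saline ones. A smaller or reversed value there does not show that the mix of clusters made the difference. Interferon medians in ASPC-like cells came to -0.35 (cold over saline), 1.65 (CL over saline) and 2.13 (CL over cold). In macrophage-like cells they came to -0.95, 0.68 and 1.72 in the same order. Values that reversed within these clusters were as follows. Cold over saline in ASPC-like cells there gave F3 stromal genes -0.22, immediate early genes 0.15, Arc 0.37, Top2a 0.05, Plin4 0.05, Pparg -0.53, Fabp4 -0.10, Apoe -0.12 and Mgp -0.28. For ASPC-like cells, CL over saline gave extracellular matrix genes 0.17, immediate early genes 0.12, Gpnmb 0.85, Il33 -0.45, Col4a1 0.37, Lox 0.26, Fabp4 1.02, Gdf10 0.17, Jun 0.09 and Hspb1 -0.07. CL over cold in ASPC-like cells there gave adipocyte and adipogenic genes 0.16, extracellular matrix genes 0.32, committed preadipocyte genes 0.28, F3 stromal genes 0.09, immediate early genes 0.01, Il33 -0.05, Ccl2 -0.05, Fabp4 1.12, Opcml 0.17, Lpl 0.42, Cd36 2.41, Fmo2 0.44, Gdf10 0.33, Vit 0.24, Dnajb9 0.04, Hsph1 -0.18, Hspb1 -0.29 and Rbm3 -0.21. For macrophage-like cells, cold over saline gave MHC class II genes 0.03, Cd209b -0.15, Lyz1 0.31, Cd9 -1.18, Timd4 -0.52, Chil3 1.40, H2-Aa 0.03 and H2-DMb1 0.19. CL over saline in macrophage-like cells there gave resident perivascular macrophage genes 0.27, type 2 response genes 0.04, heat shock genes 0.16, Dnase1l3 0.68, Lyve1 0.50, Ccl2 -0.51, Mmp12 1.26, Gas6 0.33, Mgl2 0.06, Ccl3 -0.25 and Hspb1 0.68. For macrophage-like cells, CL over cold gave lipid-associated macrophage genes 0.12, resident perivascular macrophage genes 0.08, glucocorticoid response genes 0.10, Dnase1l3 0.05, Lyve1 0.73, Ccl2 -0.70, Herpud1 0.10, Dnajb9 0.14, Timd4 1.30, Fcna 0.10, Mgl2 0.03 and Rbm3 -0.17. Cold over saline in endothelial-like cells there gave Selp 1.68. For endothelial-like cells, CL over saline gave Selp 0.14. Cold over saline in T cell-like cells there gave immediate early genes 0.06, Mki67 -0.02 and Top2a -0.04. For T cell-like cells, CL over saline gave Rrm2 -0.34. CL over cold in T cell-like cells there gave G2/M genes 0.09.

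With doublets kept, values were interferon response genes -1.65, immediate early genes 0.02 and Lyve1 0.10 for cold over saline in macrophage-like cells, and lipid-associated macrophage genes -0.34, Mki67 -0.25 and Lpl -0.05 for CL over saline in macrophage-like cells, and interferon response genes 3.33 and Sdf2l1 0.19 for CL over cold in macrophage-like cells, and Egr1 -0.05 and Nr4a1 -0.13 for CL over cold in endothelial-like cells. As the cells were clustered anew with doublets kept, these values are not the effect of doublets alone. Leaving out cells with a Mki67 or Top2a UMI can leave dividing cells in which neither was detected. It gave Rrm2 -0.66 for CL over cold in ASPC-like cells, and Hba-a1 0.03 for cold over saline in all cells. In T cell-like cells it gave Tyms -0.49 and Dut -0.03 for cold over saline, and Mcm4 0.08 and Dut 0.22 for CL over cold. With the mean of each cell's own CPM they were interferon response genes 3.08 for CL over saline in ASPC-like cells, and interferon response genes 1.87 for CL over saline in macrophage-like cells, and Hba-a1 0.10, Hba-a2 0.06, Fcer2a -0.01 and Ltf -0.04 for cold over saline in all cells. Centred on the median gene came interferon response genes 1.46 for CL over saline in macrophage-like cells. With at least 50 UMIs per member came epithelial genes 0.34 for cold over saline in all cells.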

Other observations

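The values in this part were chosen after they were seen, apart from the lists and class shares. NK cell-like cells numbered 58 in the saline, 84 in the cold and 67 in the CL library. In the same order, pericyte/smooth muscle-like cells numbered 118, 75 and 82, and plasmacytoid dendritic cell-like cells 145, 74 and 84. These classes missed the minimum of 100 cells in each library set for comparing expression, so their medians rest on few cells. Interferon response genes were higher in the CL than in the saline library also in monocyte-like cells, with a median of 1.49 (1.38 to 1.60), dendritic cell-like cells, 3.10 (2.73 to 3.30), B cell-like cells, 1.89 (1.29 to 2.30), plasmacytoid dendritic cell-like cells, 2.02 (1.47 to 2.56), pericyte/smooth muscle-like cells, 2.21 (1.92 to 2.63), and NK cell-like cells, 1.61 (0.84 to 1.92). In cold over saline they stood at -1.92 (-2.18 to -1.63) in monocyte-like and -0.66 (-0.89 to -0.32) in dendritic cell-like cells, but at 0.05 (-0.22 to 0.54) in B cell-like and 0.25 (-0.13 to 0.56) in pericyte/smooth muscle-like cells. MHC class II genes in monocyte-like cells were higher in the cold library, all 7 with a median of 0.88 (0.81 to 1.01), and lower in the CL library, -0.73 (-0.76 to -0.67). In NK cell-like cells they stood at 2.47 (2.13 to 3.08) and 2.84 (2.17 to 3.13), where free RNA of other cells was not excluded. Inflammatory cytokine genes in monocyte-like cells had a median of -0.93 (-1.49 to -0.75) in cold over saline and 0.25 (0.21 to 0.55) in CL over saline. The monocyte-like class was made of different clusters in each library, so its values compare different mixes and were not computed within a cluster. Cluster 2, with Irg1, Rsad2 and Cxcl2 among its top genes, held 32.2% of its saline, 1.58% of its cold and 58.6% of its CL cells, and cluster 16, with Treml4 and Ear2, held 16.6%, 69.5% and 3.28%. Of the B cell-like cells, cluster 8 held 21.8%, 23.2% and 42.2%.

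All 16 G2/M genes were higher in dendritic cell-like cells of both treated libraries, with medians of 0.67 (0.49 to 0.95) in the cold and 1.02 (0.81 to 1.27) in the CL comparison with saline. The cycling cluster 21 held 5.41% of the saline, 6.15% of the cold and 9.36% of the CL dendritic cell-like cells, and cluster 9 held 42.3%, 50.8% and 23.5%, so the mix of clusters differed as well. In NK cell-like cells, S-phase genes stood at 1.19 (0.77 to 1.52) and G2/M genes at 1.00 (0.48 to 1.27) in CL over saline. Heat shock genes in plasmacytoid dendritic cell-like cells were lower in both, -2.59 (-2.90 to -2.42) and -1.37 (-1.56 to -1.07). The median over all genes was 0.17 in NK cell-like cells of CL over saline, and 0.16 and 0.11 in plasmacytoid dendritic cell-like cells of the cold and CL comparisons.

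The peptide transporter gene Slc15a2 was higher in the cold than in the saline library in each class with at least 50 cells in both except Schwann-like cells, where 3 against 0 UMIs left the intervals overlapping. In B cell-like cells it was at 135 (123 to 147), 10.4 (7.19 to 14.7) and 64.1 (42.3 to 93.3) CPM in the cold, saline and CL libraries, and in dendritic cell-like cells at 59.1 (50.9 to 68.2), 4.51 (2.83 to 6.83) and 15.1 (10.7 to 20.6) CPM. Neutrophil-like cells made up 0.068%, 1.01% and 0.943% of the immune-like cells that passed in the saline, cold and CL libraries. Among the barcodes left out for under 500 genes neutrophil markers stood in another order, at 483, 113 and 3790 CPM, so these shares do not rank the libraries. An unnamed cluster, 23, had Ighg2b, Igha, Jchain and Mki67 among its top genes and held 18 saline, 85 cold and 4 CL cells. Plasmacytoid dendritic cell-like cells made up 3.27%, 2.57% and 1.62% of immune-like cells. In CL cells Saa3 was at 14100 CPM in macrophage-like, 2600 in monocyte-like and 2030 in ASPC-like cells, and between 25.4 and 57.6 CPM in lymphoid, endothelial-like, pericyte/smooth muscle-like and dendritic cell-like cells.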
